A study of Mus musculus with 12 samples.

How the data were processed

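RNA was sequenced from CT26 cells, a mouse colorectal cancer line, and from CT26 tumors grown under the skin of mice. The labels place the 12 libraries in 4 groups of 3. Cells received either the solvent DMSO or midostaurin, a multikinase inhibitor, at 1 µM for 48 h. Tumors received either vehicle or midostaurin at 40 mg/kg, starting on day 7 after inoculation and lasting 2 weeks. Per the labels' protocols, RNA was isolated with TRIzol and turned into directional poly(A)-selected libraries with a NEBNext kit. Nothing in the labels says whether the 3 samples of a group came from separate cultures or animals, so the p-values measure the spread between these samples, which for the cells may be technical.

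The deposited values are whole-number counts per gene, in 1 table for the cells and 1 for the tumors, each with 55335 Ensembl gene identifiers. Per the submitters' processing notes, the tools were FastQC 0.11.2, Bowtie2 2.3.4 and RSEM (version not given in the sources used here), with the mm10 mouse genome. RSEM shares reads among overlapping and similar genes by an estimate, and rounding of such estimates before deposit cannot be told from whole counts. Neither the gene annotation nor the strand setting of the counting is given in the sources used here. Symbols were taken from a table of mouse gene identifiers, which named 99.7% of them and left 181 without a symbol, and gene positions from a GENCODE annotation of the same genome build. All value columns of both tables were mapped to a group. The labels number the treated tumors 1 to 3, while the columns of the table number them 2 to 4. The columns numbered 2 and 3 were matched to the labels of those numbers, and the column numbered 4 was used as a midostaurin tumor with no number of its own in the labels. It is called midostaurin tumor 4 here.

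Total counts were 34787389 to 38144039 per cell library and 33399701 to 48109497 per tumor library. Between 19637 and 20088 genes were detected in a cell library and between 21382 and 22145 in a tumor library.

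Differential expression was tested with edgeR 4.0.16 (R 4.3.3) on the counts as deposited. Genes were filtered with filterByExpr, libraries were scaled by TMM, and the quasi-likelihood F-test was applied with a Benjamini-Hochberg adjusted p threshold of 0.05. Cells and tumors were fitted separately. The difference between the tumor and the cell response was tested as an interaction in 1 fit over all 12 libraries. Expression values are TMM-scaled CPM (each count relative to the scaled total of its library), computed here from the deposited counts. Standard errors of log2 fold changes come from the same fits.

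Before the data were examined, 39 gene lists were fixed (pathways, reported targets of midostaurin, cell type markers and signs of RNA quality). Lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation of 0.01), adjusted over the lists. Camera with an estimated correlation and directional fry were alternatives, and the mixed test of fry was also computed. Unlike camera, fry does not compare a list with the other genes. Members were also counted with p adjusted over their list alone, and the share of random lists that would pass this way was not computed. For H2-L and Ahsp no identifier carried the symbol. A per-library list score is the mean over members of log2(CPM + 0.5), centred over the libraries of the experiment.

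Genes named in the text were chosen by a rule also fixed beforehand. In each experiment it takes the 10 largest changes per direction among genes past the threshold, with a mean of at least 5 CPM and no overlap between the groups, leaving out predicted genes and receptor segments. Where no gene passes, it takes the 5 smallest p-values. It adds up to 4 members of each list with the smallest p, and always Trex1, Tmem173, Cgas, Cd274, Kit, Flt3, Cdkn1a, Mki67, Cd8a and Foxp3 where tested. For the difference it takes 5 genes per direction. Any other gene is said to be chosen after its values were seen.

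The control and midostaurin groups share replicate numbers. In cells, the deviations from the group means of same-numbered libraries correlated across genes at 0.82, 0.56 and 0.56 for numbers 1, 2 and 3. Between numbers 2 and 3 they correlated at 0.44 and 0.41, and between number 1 and the others at -0.64 to -0.62. The correlations thus mainly set number 1 apart. The noise ratio explained below was 3.26 to 3.37 for same-numbered pairs and at least 7.13 for all other pairs. On that basis the numbers pair the cell libraries, by the data and not by any statement in the labels. A fit with the number as a block is therefore given beside cell results where it changes them, and a fit with the block in cells alone beside the difference. In tumors only numbers 2 and 3 are shared, and their correlations were 0.10 and -0.18. For every pair of libraries of 1 experiment, the counts were also compared with sampling noise, over genes with a summed count of at least 50. The noise ratio is the median chi-square over that of pure sampling. The extra coefficient of variation comes from the rise of that ratio from genes with a mean count under 250 to those of at least 2500. It takes off the ratio of the first set and not the value of 1 for pure sampling, so it leaves out noise shared by genes with few counts.

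The tests were checked on simulated counts drawn from the means and library sizes of these data, with known changes. Genes were drawn independently of each other, so the rates do not cover the correlation between genes in the real data. In simulated tumors, 6.1%, 43.8% and 79.4% of genes changed by 0.5, 1 and 2 on the log2 scale were called, with 5 false calls among 87. In simulated paired cells the fit with the block called 75.0%, 86.4% and 100% of them, with 22 false calls among 191, and the fit without it called 0%, 27.3% and 60.7%. For the difference, 0%, 6.2% and 50.0% were called. With 1 list raised by 0.5 in simulated tumors, camera called that list and 1 unchanged list.

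Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors within edgeR, no filter, a filter of 1 CPM in at least 3 libraries, a minimum absolute log2 fold change of 1, the replicate block, 1 fit over all libraries for each experiment, and leaving out each library in turn. Added after the data were seen were fits without the cell libraries numbered 1, fits on counts summed over genes that overlap on the same strand, a fit without control tumor 1 and midostaurin tumor 3, and the block in cells alone for the difference. Python 3.11.15 was used for preparation and figures.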

Results

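The data cover CT26 cells in culture and CT26 tumors in mice, each with and without midostaurin, with 3 libraries in each of the 4 groups. Midostaurin inhibits several kinases, FLT3, KIT and protein kinase C among them. The design asks what the drug changes in the cancer cells themselves, what it changes in the tumor, which also holds immune and stromal cells, and whether the responses differ. Each cell library held 34787389 to 38144039 counts and each tumor library 33399701 to 48109497.

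The libraries of cultured CT26 cells labelled with 48 h of 1 µM midostaurin lay close to those of the DMSO controls. Each lay nearer to the control library of its own number than to any other library, so the values below compare libraries and leave open whether the drug acted on the cells. Mki67, a proliferation marker, measured 210.0 ± 61.8 CPM in controls and 211.7 ± 56.1 CPM with the drug (mean ± SD, n = 3 each). Cdkn1a, a cell cycle inhibitor under p53, measured 278.8 ± 22.7 and 282.2 ± 28.0 CPM. Tmem173, which encodes the DNA-sensing adaptor STING, measured 46.5 ± 6.25 and 45.8 ± 4.79 CPM, and Cd274, which encodes PD-L1, 4.81 ± 3.09 and 4.39 ± 2.61 CPM. Each of these differences was smaller than the spread between replicates. Across genes that spread followed the replicate numbers, as described below, so it says little about differences within same-numbered pairs.

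None of the 14538 genes tested in cells passed the threshold with edgeR, and 75 had an unadjusted p below 0.05 (629 with the replicate block), where 727 would be expected by chance. DESeq2 and limma-voom each called 2. Across the 10447 genes with at least 5 CPM, the median absolute log2 fold change was 0.04 in the fit with the replicate number as a block. In that fit the 95% interval of 99.8% of these genes lay within a 2-fold change.

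With the replicate block, 8 genes were called in cells, 5 higher and 3 lower with midostaurin. In simulated paired cells this fit gave 22 false calls among 191, a share above the threshold of 0.05. In the real data, another split of the same pairs called 7 genes. Phc3, a Polycomb group gene (ENSMUSG00000037652, mm10 chromosome 3, 30899371 to 30969415), measured 19.2 ± 1.44 CPM in controls and 69.1 ± 7.01 CPM with the drug, a log2 fold change of 1.85 ± 0.05 (SE, adjusted p = 1.48e-09 with the block and 0.0526 without it). H2-T3, a nonclassical MHC class I gene (ENSMUSG00000054128, chromosome 17, 36185572 to 36190287), had 42, 31 and 37 counts in the controls and 0 in each midostaurin library. Against a floor of 3 counts per library it was at least 11.9-fold lower (adjusted p = 0.011 with the block and 1 without it). Reads of H2-T3 can be shared with other members of its gene family. The other 6 called genes were Gm29253, 4933427D14Rik, Mrpl53 and Zfp862-ps, which were higher, and Gm43951 and Lrch4, which were lower. All 6 overlap another gene on the same strand, so their split of reads is uncertain, and they were named after their values were seen. In tumors the counts of Phc3 varied within the groups, with 1331, 281 and 1477 in controls and 1459, 223 and 182 with midostaurin. Of the other genes with the smallest p, Sp4 measured 6.16 ± 1.13 and 2.96 ± 0.645 CPM (adjusted p = 1, and 0.0527 with the block). With the block and counts summed over overlapping genes, Sp4 and Malat1, a nuclear noncoding RNA named after its values were seen, were called too, at log2 fold changes of -1.06 ± 0.16 and -0.19 ± 0.03 (adjusted p = 0.00673 each). AC166110.2 and Hist1h1e stayed below 1 CPM in both groups and had adjusted p = 1.

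No gene list was called in cells. The medians of the 25 lists tested lay between -0.18 and 0.21 on the log2 scale, and the smallest adjusted p from camera was 0.983 (0.19 with the block). No list member passed the threshold without the block, either over all genes or adjusted over the list alone. With the block, 4 of 13 mitochondrially encoded mRNAs, 1 of 17 extracellular matrix genes and 1 of 5 monocyte markers were higher adjusted over the list alone. Among 7 tested kinases reported as midostaurin targets, Prkca measured 42.4 ± 4.85 CPM in controls and 44.9 ± 4.05 CPM with the drug, and Syk 9.93 ± 2.04 and 10.9 ± 4.50 CPM. In the interferon list, with 28 tested members, Stat2 measured 75.2 ± 17.7 and 72.4 ± 16.1 CPM. In the ERK output list, with 20 tested members, Etv4 measured 108.9 ± 26.8 and 102.6 ± 26.9 CPM. In the mitosis list, with 28 tested members, Plk1 measured 122.5 ± 26.6 and 129.0 ± 27.9 CPM.

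The wide spread within each cell group followed the replicate numbers. The same-numbered control and midostaurin libraries differed by an extra coefficient of variation of 2.13% to 2.32%. Libraries of the same treatment with different numbers differed by 7.14% to 28.0%. In genes with a mean count under 250, whose noise this measure takes off, the noise ratio was 2.59 to 2.88 for the same-numbered pairs. For the same-treatment pairs it was 3.58 to 11.8. The first principal component, with 69.3% of the variance, set the libraries numbered 1 of both treatments (-64.3 and -64.2) apart from those numbered 2 and 3 (30.1 to 34.1). The same-numbered pairs still differed by more than sampling alone, with a noise ratio of 3.26 to 3.37 where sampling gives 1, and were kept as separate libraries. Reads shared among genes by an estimate may add to this ratio, which was not tested. The ratio therefore does not show that the libraries of a pair came from separate RNA.

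**Figure D1:**
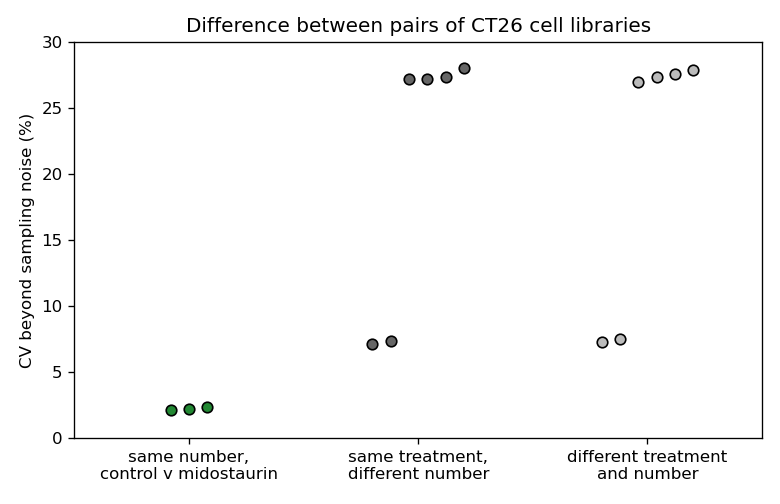
Extra coefficient of variation between pairs of CT26 cell libraries, from the rise of the noise ratio between genes with low and high counts, in percent (vertical axis). There is 1 point per pair, for 3 pairs of the same number, 6 of the same treatment and 6 others. The 3 same-numbered control and midostaurin pairs lie between 2.13% and 2.32%, below all other pairs.

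In CT26 tumors, midostaurin treatment was accompanied by higher Thbs2, Il7, Csrp2, Lxn and Hivep1 and lower Sncg and Ak5. Thbs2, which encodes the matrix protein thrombospondin 2, rose 4.86-fold, from 125.5 ± 21.6 CPM in control tumors to 609.8 ± 154 CPM (mean ± SD, n = 3 each). Il7, a cytokine that sustains lymphocytes, rose 4.74-fold, from 4.17 ± 0.707 to 19.8 ± 3.79 CPM. Sncg, which encodes gamma-synuclein, fell from 16.99 ± 3.76 to 4.05 ± 0.11 CPM. In each of these genes all 3 treated tumors lay on 1 side of all 3 controls.

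These were the 7 genes that passed the threshold among 16094 tested with edgeR, each with an adjusted p of 0.0377. Thbs2 (ENSMUSG00000023885, mm10 chromosome 17, 14665500 to 14694235) had a log2 fold change of 2.28 ± 0.21 (SE), and Il7 (ENSMUSG00000040329, chromosome 3, 7569994 to 7613760) of 2.24 ± 0.20. Csrp2, a LIM domain gene of muscle and stellate cells (ENSMUSG00000020186, chromosome 10, 110919789 to 110939622), rose by 1.65 ± 0.14, from 34.4 ± 6.21 to 107.5 ± 2.72 CPM. Lxn, a carboxypeptidase inhibitor (ENSMUSG00000047557, chromosome 3, 67457998 to 67463926), rose by 1.63 ± 0.15, from 108.3 ± 8.98 to 334.2 ± 62.9 CPM. Hivep1, a zinc finger transcription factor (ENSMUSG00000021366, chromosome 13, 42052021 to 42192537), rose by 0.79 ± 0.07, from 44.6 ± 0.998 to 77.1 ± 1.73 CPM. Sncg (ENSMUSG00000023064, chromosome 14, 34370274 to 34374789) fell by 2.07 ± 0.19. Ak5, an adenylate kinase (ENSMUSG00000039058, chromosome 3, 152462815 to 152668360), fell by 1.25 ± 0.12, from 33.9 ± 3.82 to 14.3 ± 0.952 CPM.

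**Figure D2:**
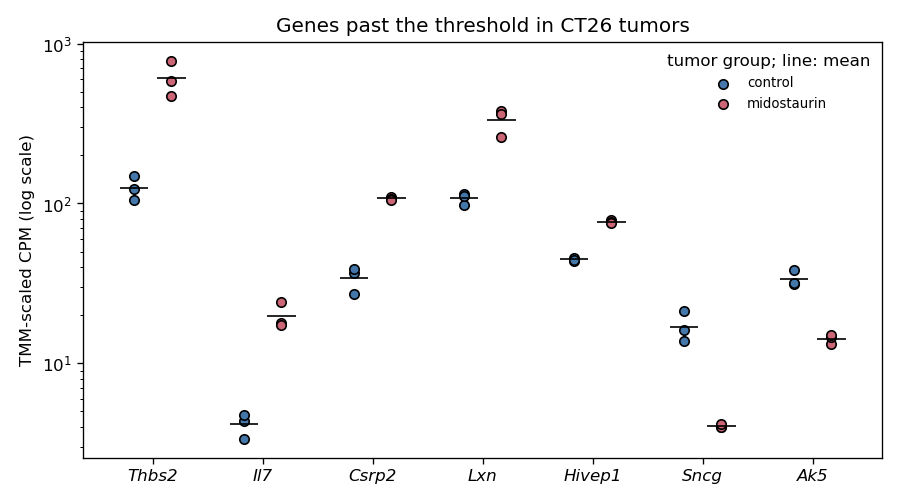
TMM-scaled CPM (log scale) of the 7 genes past the threshold in each control tumor and each midostaurin tumor, with 1 point per library and a line at the mean of each group. The groups do not overlap in any of the 7 genes, and Hivep1 lies at 43.7 to 45.7 CPM in controls and 75.5 to 78.9 CPM with midostaurin.

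Beyond these genes, 3205 genes (19.9%) had an unadjusted p below 0.05, where 805 would be expected by chance, and in 27.2% of genes the groups did not overlap, where chance gives 10%. DESeq2 called 1447 genes, 874 higher and 573 lower, all 7 above among them, and limma-voom called 16. No gene passed with edgeR without the low-count filter, and 0 or 1 passed when any 1 tumor library was left out. Csrp2 alone kept its call in such a fit, without control tumor 1, and the adjusted p of all 7 genes ranged up to 0.197 across these fits.

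Several immune genes lay just outside the edgeR threshold and inside that of DESeq2. Cd274 measured 21.3 ± 3.29 CPM in controls and 60.6 ± 12.1 CPM with the drug (log2 fold change 1.51 ± 0.18, adjusted p = 0.0672 with edgeR and 3e-11 with DESeq2). Pdcd1lg2, which encodes the related ligand PD-L2, had a log2 fold change of 2.71 ± 0.52 (adjusted p = 0.085 and 9.12e-05), and Ido1, a tryptophan-degrading enzyme, of 1.72 ± 0.32 (0.0848 and 0.000101). The checkpoint list as a whole was not called (adjusted p = 0.0895 with camera, and 0.000674 with the mixed test of fry), with 3 higher and 1 lower of its 19 members adjusted over the list alone. The other genes fixed in advance did not pass with edgeR, nor with DESeq2, which gave no adjusted p for Foxp3 and Flt3. Mki67 measured 266.3 ± 11.0 and 271.7 ± 1.57 CPM, Cdkn1a 196.5 ± 25.0 and 226.8 ± 32 CPM, and Tmem173 49.98 ± 2.35 and 60.1 ± 21.6 CPM. Trex1, a DNase that clears cytosolic DNA, measured 5.46 ± 2.70 and 6.28 ± 2.59 CPM, and Cgas, a DNA sensor, 24.9 ± 0.159 and 20.1 ± 3.58 CPM (adjusted p = 0.292 with edgeR). Cd8a, a marker of cytotoxic T cells, measured 8.99 ± 2.37 and 9.77 ± 4.09 CPM, and Foxp3, of regulatory T cells, 0.588 ± 0.155 and 0.688 ± 0.421 CPM. Kit measured 5.43 ± 0.985 and 6.05 ± 0.828 CPM, and Flt3 stayed near 1 CPM or below.

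Camera called 15 of the 38 lists tested in tumors, 9 higher and 6 lower, none of them with an estimated correlation and 1 with directional fry. The mixed test of fry, which asks whether members change in either direction, called 7 lists in tumors and 0 in cells and for the difference. Fry does not compare a list with the other genes. With 19.9% of all tumor genes at an unadjusted p below 0.05, its calls in tumors do not set a list apart from genes at large. Of the 15 camera calls, 7 held without any 1 library. Among the cell type markers, the macrophage list was lower with midostaurin, with 16 of 17 tested members below 0 and a median log2 fold change of -0.78 (camera adjusted p = 5.32e-07; p = 0.126 with an estimated correlation). The median was -0.50 without midostaurin tumor 2. Mrc1, a mannose receptor of tissue macrophages, measured 272.6, 103.5 and 175.5 CPM in the 3 controls and 24.1, 85.5 and 62.2 CPM with the drug (adjusted p = 0.152). Trem2, a lipid receptor of macrophages, had a log2 fold change of -0.89 ± 0.19 (adjusted p = 0.0936). None of the members passed over all genes, and 1 passed adjusted over the list alone. The list score was -1.06 in midostaurin tumor 2, -0.23 in tumor 4 and 0.06 in tumor 3, against 0.13 to 0.69 in controls. Pericyte and smooth muscle markers were also lower as a list (median -0.30, adjusted p = 0.0218; p = 0.264 with an estimated correlation), a call lost without control tumor 1 (median -0.19, adjusted p = 0.0753) or midostaurin tumor 2 (-0.14, 0.166). Their median was -0.47 without control tumor 2, -0.62 without control tumor 3 and -0.66 without midostaurin tumor 3 or 4.

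Neutrophil markers were higher, with a median log2 fold change of 2.71 and all 13 tested members above 0 (adjusted p = 0.000811; p = 0.298 with an estimated correlation). Inflammatory NF-kB targets were higher in 20 of 21 members (median 0.99, adjusted p = 0.000145; p = 0.331 with an estimated correlation). Both calls were lost without midostaurin tumor 3, where the medians were 0.39 (adjusted p = 0.252) and 0.20 (adjusted p = 0.267). Il1b measured 392.8 CPM in that tumor and 5.92 to 26.4 CPM in the other 5. No member of either list passed, adjusted over all genes or over the list alone. Chemokines were not called as a list (adjusted p = 0.203). In that list Cxcl1 measured 832.1 CPM in midostaurin tumor 3 and 6.04 to 14.6 CPM elsewhere, while Ccl7, a monocyte attractant, had a log2 fold change of -1.20 ± 0.29 (adjusted p = 0.11).

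Lysosome and autophagy genes were higher in 20 of 26 members, with a median log2 fold change of 0.24 (adjusted p = 0.000212; p = 0.0282 with an estimated correlation, which did not pass adjusted over the 38 lists). This was the 1 list called by directional fry (adjusted p = 0.042; 0.0155 with the mixed test), with 12 members higher and 1 lower adjusted over the list alone and none over all genes. Npc2 and Npc1, which move cholesterol out of lysosomes, had log2 fold changes of 0.39 ± 0.09 and 0.55 ± 0.13 (adjusted p = 0.101 and 0.108), and Tfe3, a regulator of lysosomal genes, of 0.37 ± 0.08 (adjusted p = 0.0939). The list's scores were -0.15 to -0.08 in controls and 0.09 to 0.13 in treated tumors. Targets of the aryl hydrocarbon receptor, a xenobiotic sensor, were higher in 5 of 6 members (median 0.98, and 1.61 without control tumor 1, adjusted p = 0.00376; p = 0.0286 with an estimated correlation). Aldh3a1 measured 3.17 to 10.2 CPM in controls and 32.2 to 127.8 CPM with the drug, a log2 fold change of 3.26 ± 0.64 (adjusted p = 0.0874). Cholesterol synthesis genes were higher in 22 of 24 members (median 0.26, adjusted p = 0.00121; p = 0.357 with an estimated correlation), and 1 passed adjusted over the list alone. That call was lost without control tumor 3 (median 0.20, adjusted p = 0.14) or midostaurin tumor 2 (0.07, 0.132). Hypoxia and glycolysis genes were higher in 19 of 22 members (median 0.39, adjusted p = 0.000484; p = 0.34 with an estimated correlation), a call lost without control tumor 3 (median 0.22, adjusted p = 0.14). The hypoxia median was 0.23 without midostaurin tumor 2 and 0.70 without control tumor 2.

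Type I interferon response genes were higher in 29 of 30 members, with a median log2 fold change of 0.38 (adjusted p = 0.000214; p = 0.4 with an estimated correlation). The list's scores were -0.02, 0.02 and -0.48 in controls 1, 2 and 3 and 0.57, -0.30 and 0.21 in midostaurin tumors 2, 3 and 4, so the groups overlapped, and no member passed adjusted over the list alone. Ifih1, a sensor of viral RNA, had a log2 fold change of 0.44 ± 0.13 (adjusted p = 0.141). Without midostaurin tumor 2 the median was 0.16 (adjusted p = 0.14), and without control tumor 3 it was 0.24 (adjusted p = 0.0686). MHC class I genes (median 0.14, adjusted p = 0.027; p = 0.305 with an estimated correlation) and MHC class II genes (median 0.87, adjusted p = 0.0256; p = 0.404 with an estimated correlation) were higher too. The class I call was lost without control tumor 1, control tumor 3 or midostaurin tumor 2 (adjusted p = 0.0621, 0.0861 and 0.174), and the class II call without control tumor 2, control tumor 3, midostaurin tumor 3 or midostaurin tumor 4 (0.231, 0.0569, 0.252 and 0.113). The class I median was 0.23 without control tumor 2, and the class II median 0.57 without midostaurin tumor 3. Ciita, the master regulator of class II genes, had a log2 fold change of 1.86 ± 0.34 (adjusted p = 0.0841), while Ifi30, a lysosomal reductase, had -0.74 ± 0.16 (adjusted p = 0.0943). Genes of cytosolic DNA sensing were not called by camera (median 0.03, adjusted p = 0.911), and their members went both ways (adjusted p = 0.0152 with the mixed test of fry). Adjusted over the list alone, 1 of 17 was higher and 1 lower, and the smallest p were those of Ifi204 and Rnaseh2a, with log2 fold changes of 0.41 ± 0.07 and -0.41 ± 0.08 (adjusted p over all genes = 0.0841 and 0.0869).

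Camera called both lists of proliferation genes lower. The list of G1/S and DNA replication had 27 of 29 members below 0 (median -0.31, adjusted p = 8.21e-05; p = 0.358 with an estimated correlation), and that of mitosis 25 of 28 (median -0.20, adjusted p = 0.000484; p = 0.315 with an estimated correlation). Without control tumor 1 the medians were -0.20 and -0.09, and without midostaurin tumor 3 they were -0.18 and -0.13. The G1/S scores of midostaurin tumors 2 and 4 (0.02 and 0.00) lay above that of control tumor 2 (-0.06). No member of either list passed, and Mcm6, a replicative helicase subunit, had a log2 fold change of -0.50 ± 0.19 (adjusted p = 0.206). Markers of T cells, cytotoxic effectors, natural killer cells, regulatory T cells, B cells, monocytes, dendritic cells, mast cells, endothelium, fibroblasts, skeletal muscle and keratinocytes were not called, nor were p53 targets, ERK output, the unfolded protein response, SRF and YAP targets, NRF2 targets, extracellular matrix, reported midostaurin target kinases and immediate early genes. Adjusted over the list alone, 4 of 22 ERK output genes were higher, and Spry2 and Phlda1 had the smallest p in that list, with log2 fold changes of 0.76 ± 0.15 and 1.17 ± 0.25 (adjusted p over all genes = 0.085 and 0.0939). Lower on that basis were 3 of 22 genes of the unfolded protein response, 3 of 8 B and plasma cell markers and 1 of 21 p53 targets. Of 12 monocyte markers 1 was higher and 2 lower, and 1 marker each of regulatory T cells and dendritic cells was higher. Among all tumor genes 19.9% had an unadjusted p below 0.05. These counts were not compared with random lists, so they do not set these lists apart. The mixed test of fry called ERK output, B and plasma cells, monocytes and p53 targets (adjusted p = 0.0155, 0.0272, 0.0152 and 0.032). The camera adjusted p of these lists without a call ranged from 0.052 for ERK output to 0.973 for extracellular matrix. With 1 library left out, 13 lists without a call gained 1 in at least 1 fit. Cytotoxic effectors had a median of -0.66 without midostaurin tumor 2 (adjusted p = 0.000242), and dendritic cell markers 0.66 without control tumor 1 (0.000246). Skeletal muscle markers had -3.73 without midostaurin tumor 3 (0.000319), and keratinocyte markers -3.56 without control tumor 1 (0.000171).

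Signs of tissue makeup and RNA quality differed between the groups beside these lists. All 13 mitochondrially encoded mRNAs were lower with midostaurin (median -0.82, adjusted p = 5.74e-05; p = 0.227 with an estimated correlation). Their share of counts was 2.16%, 2.84% and 2.88% in controls and 1.55%, 1.08% and 2.48% in midostaurin tumors 2, 3 and 4. The median was -0.46 without midostaurin tumor 3 and -1.39 without midostaurin tumor 4. Erythroid genes were lower (median -3.70, adjusted p = 0.00583; p = 0.228 with an estimated correlation), all 5 members adjusted over the list alone, and their median was -1.92 without control tumor 1 (adjusted p = 0.0418). Hemoglobin transcripts, without TMM scaling, measured 2006.5, 30.8 and 443.4 CPM in control tumors 1, 2 and 3 and 16.0 to 112.0 in treated tumors. Control tumor 2 held keratinocyte transcripts, with Krt10 at 30.5 CPM against 1.15 to 1.46 CPM in the other tumors.

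**Figure D3:**
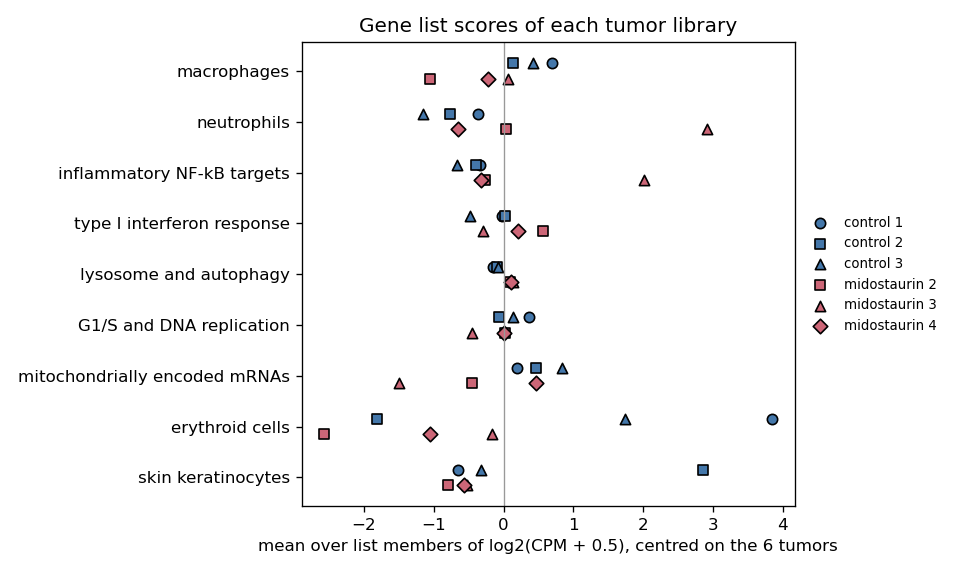
Mean over list members of log2(CPM + 0.5), centred on the 6 tumors (horizontal axis), for 9 gene lists, with 1 point per tumor library. Midostaurin tumor 3 stands at 2.91 for neutrophil markers and control tumor 1 at 3.85 for erythroid genes, while lysosome scores of treated tumors (0.09 to 0.13) lie above those of controls (-0.15 to -0.08).

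The responses of tumors and cells were compared directly, and H2-T3 was the 1 gene among 16965 whose response differed past the edgeR threshold. It measured 5.02 ± 0.781 CPM in control tumors and 4.79 ± 0.852 CPM in treated tumors, against 0.986 ± 0.124 CPM in control cells and 0 in treated cells (n = 3 each, adjusted p = 0.00591 with edgeR). With the block in both experiments, whose numbers do not pair the tumors, H2-T3 did not pass (adjusted p = 0.0672), and with the block in cells alone it did (0.0287). Kcnab2, a potassium channel subunit, Lxn and Hivep1 were among the next smallest p-values without passing. For Kcnab2 the tumor effect lay 1.65 ± 0.21 below the cell effect on the log2 scale (adjusted p = 0.0565), and for Lxn 1.62 ± 0.22 above it (adjusted p = 0.0763). Lxn measured 40.4 ± 5.03 and 40.3 ± 5.48 CPM in cells without and with the drug.

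For Hivep1 the tumor effect lay 0.75 ± 0.11 above the cell effect (adjusted p = 0.126). Arhgap25 was also among the smallest p-values (adjusted p = 0.0565), with 8.18 ± 0.800 and 5.89 ± 1.09 CPM in control and treated tumors against 0 and 0.188 ± 0.0481 CPM in control and treated cells, too few counts in cells for a fold change. Unadjusted, 1032 genes had a p below 0.05, where 848 would be expected by chance, and DESeq2 called 99 genes. With the replicate block in cells alone the count was 16, with Kcnab2, Lxn and Hivep1 past the threshold (adjusted p = 0.0421, 0.0287 and 0.0287). Without the cell libraries numbered 1 it was 0, with H2-T3 at an adjusted p of 0.0529. Fits of the difference estimate 1 dispersion per gene over cells and tumors. The biological coefficient of variation of the separate fits was 5.5% in cells with the block and 25% in tumors without it. Whether the genes and lists called with the block depend on this pooling was not tested.

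Camera called 10 lists for the difference, 6 with a higher and 4 with a lower response in tumors than in cells, and none with an estimated correlation. Mitochondrially encoded mRNAs differed by a median of -0.81 (camera adjusted p = 6.59e-08, and p = 0.0992 with an estimated correlation). Aryl hydrocarbon receptor targets, with 6 tested members against 4 in the cell fit, differed by 1.40 (adjusted p = 0.00133, and p = 0.00453 with an estimated correlation, which did not pass adjusted over the lists). These were the 2 calls that held without any 1 library, and the mitochondrial median was -0.46 without midostaurin tumor 3 and -1.42 without midostaurin tumor 4. With the replicate block in cells alone, camera called 11 lists. Type I interferon (median 0.32, adjusted p = 0.0263), MHC class I (0.17, 0.0253) and ERK output (0.18, 0.044) were then called, while neutrophil and keratinocyte markers were not (adjusted p = 0.102 and 0.0934), and again none was called with an estimated correlation. Of the 7 genes called in tumors, 6 were tested in cells too, where none was called. Across 10090 genes with at least 5 CPM, the log2 fold changes of tumors and cells had a Pearson correlation of -0.055 and a Spearman correlation of -0.014, across genes, which are not independent replicates. In cells the median absolute log2 fold change (0.036) lay below the median SE (0.05) in the fit with the block. A low correlation therefore says little about whether the responses are related.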

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

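The tests of the same-numbered cell libraries, of the genes called in cells with the replicate block and of the neutrophil and NF-kB lists were chosen after those results were seen, as were the splits of the cell libraries without the block and those of the difference with the block in cells alone. The splits of the tumors, of the difference without the block and of the blocked cell fit were set out before their results were seen.

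H2-T3 and 10 gene lists differed between the tumor and the cell response by a test of the difference itself. The fitted difference of H2-T3 was 8.18 on the log2 scale, which depends on the prior count because treated cells had 0 counts. The lists with a higher response in tumors were NF-kB targets (median difference 1.18, p = 0.183 with an estimated correlation), hypoxia and glycolysis (0.41, p = 0.164), aryl hydrocarbon receptor targets (1.40, p = 0.00453), cholesterol synthesis (0.27, p = 0.321), lysosome and autophagy (0.24, p = 0.421) and neutrophil markers (3.64, p = 0.273). Neutrophil markers had 11 tested members for the difference and 3 in cells, and aryl hydrocarbon receptor targets 6 and 4. Members with too few counts in cells for the filter give little cell response to compare, and both medians partly rest on such genes. Lower in tumors were the lists of DNA replication and G1/S (-0.33, camera p = 0.433 with an estimated correlation), mitosis (-0.21, p = 0.503), keratinocyte markers (-2.80, p = 0.181) and mitochondrially encoded mRNAs (-0.81, p = 0.0992). In 20 of 100 drawn splits of the samples, the real one included, at least 1 gene was called for the difference in the fit without the block (real value 1, highest other 10), so chance is not excluded for that count. Those splits also break the cell pairs. With the block in cells alone, 2 of the 80 splits that part every cell pair, the real one included, gave at least 16 genes. That share is under 0.05 (real value 16, highest other 17). The counts followed the tumor groups, with 3 to 17 for the real tumor groups, 5 to 10 for these swapped and 0 to 2 for mixed ones. The 80 splits only cross 10 ways of grouping the tumors with 4 of grouping the cells. Each is too few for such a share, so chance is not excluded for this count either. With the real tumor groups kept, regrouping the cells gave 17, 6 and 3 genes, so the count also moved with the cell groups.

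Camera's call of 8 of these lists was lost without at least 1 library. Leaving out 1 cell library leaves its same-numbered partner unpaired, so these fits, made without the block, carry differences between the numbers (a median of -0.65 for lysosome genes between number 1 and the others) into the comparison. With the block in cells alone and all libraries, camera called lysosome genes (adjusted p = 0.000262), G1/S and mitosis (4.16e-05 each) and cholesterol synthesis (0.000488), but none of them with an estimated correlation. For NF-kB targets the median was 0.23 without midostaurin tumor 3 (adjusted p = 0.169). Neutrophil markers had 0.32 without midostaurin tumor 3 (0.218), and 2.90 to 3.90 in the fits without control cells 2 or 3, midostaurin cells 1, or control tumor 2 or 3, where the call was also lost (0.0619 to 0.496). Lysosome genes had 0.02 without midostaurin cells 1 (0.901), 0.09 and 0.12 without control cells 2 and 3 (0.386 and 0.196) and 0.17 without midostaurin tumor 3 (0.0612). The G1/S list had -0.04 without midostaurin cells 1 (0.544), -0.16 without control cells 2 (0.238), -0.21 without control tumor 1 (0.1) and -0.19 without midostaurin tumor 3 (0.169). It kept its call without control cells 1, at -0.54. The mitosis list had -0.02 without control cells 2 (0.966), -0.07 and -0.14 without midostaurin cells 1 and 3 (0.427 and 0.313), -0.13 without control tumor 1 (0.171) and -0.17 without midostaurin tumor 3 (0.0818). It kept its call at -0.34 without control cells 1 and -0.39 without midostaurin cells 2. Cholesterol synthesis genes had 0.07 without midostaurin tumor 2 (0.263), 0.12 without midostaurin cells 1 (0.298), and 0.18 without control cells 2, control cells 3 or control tumor 3 (0.0619, 0.065 and 0.173). Hypoxia genes had 0.23 without control tumor 3 (0.0523), and kept their call at 0.27 without midostaurin tumor 2 and 0.71 without control tumor 2. Keratinocyte markers had -0.09 without control tumor 2 (0.831), and -4.20 to -2.91 in the other fits that lost the call (0.0669 to 0.237), each without 1 library other than midostaurin cells 1, control tumor 1 and control tumor 3. Of the calls that held, mitochondrially encoded mRNAs had -0.46 without midostaurin tumor 3 and -1.42 without midostaurin tumor 4.

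The same-numbered control and midostaurin cell libraries differed less than any other pair, with a largest extra coefficient of variation of 2.32%, against 7.14% for the closest same-treatment pair. A shared RNA or library behind both treatment names may account for this, since the largest noise ratio was 3.37 against 7.13 for the closest other pair, but so may cultures paired by number with no response to the drug in most genes. Phc3 (684 to 705 counts in controls and 2338 to 2669 with midostaurin) and H2-T3 (31 to 42 and 0) differed in all 3 pairs. This goes against a shared RNA or library as a full account unless their reads were assigned differently in the libraries, which stays open. Sp4 and Malat1 were also called with the block once overlapping genes were summed, and for the remaining genes, with 0 same-treatment pairs sharing a number, these explanations cannot be told apart. With a real count of 0 called genes, all 10 splits of the cell libraries give as many by construction (highest other 0), which says nothing about chance.

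The genes called in cells with the replicate block fell into 2 kinds. Of the 6 that overlap another gene on the same strand, 0 were called after counts were summed over overlapping genes, in line with reads moving between those genes. The other 2, Phc3 and H2-T3, have no such partner among genes of the GENCODE annotation with at least 50 counts over all libraries. This argues against that explanation for them as far as this annotation goes. Sharing of reads with similar genes elsewhere, such as the family of H2-T3, was not examined. Unstable read assignment may account for Phc3, whose range within the tumor groups (8.7-fold) lay at the 98.7th percentile of 1000 genes of similar mean. That range can also come from differences between the tumors, so it does not decide the question. In cells the Phc3 counts followed the labels, with 684 to 705 in controls and 2338 to 2669 with midostaurin. A response to midostaurin stays open for both genes. Of the 4 splits that part all pairs, the real one alone called 8 genes and the highest other called 7, and 4 splits are too few for a share under 0.05 (1 of 4).

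The neutrophil and NF-kB lists were higher in treated tumors by 2.71 and 0.99, and by 0.39 and 0.20 without midostaurin tumor 3, so the size of both may come from that tumor. S100a9, a neutrophil transcript chosen after its values were seen, measured 360.1 CPM there and 1.10 to 10.9 CPM in the other tumors. The neutrophil score lay above every control in 2 of 3 treated tumors, which does not settle whether it was higher in each, and infection, ulceration or the site sampled were not tested. For the 7 genes called in tumors, 1 of 10 splits, the real one, gave as many (real value 7, highest other 0), and 10 splits are too few for a share under 0.05.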

How the results depend on the processing

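The fits without the cell libraries numbered 1, with counts summed over overlapping genes, without control tumor 1 and midostaurin tumor 3 together, and with the block in cells alone were chosen after seeing the data. All deposited values were whole, so unrounded values, which had been foreseen, were not run. With 3 libraries per group, the simulated tumors recovered 6.1% of changes of 0.5 on the log2 scale, so most changes of that size would go uncalled. The cause of the differences below was not tested unless stated.

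The count of genes called in cells (0) was 2 with DESeq2, 2 with limma-voom, 8 with the replicate block, 1 in 1 fit over all 12 libraries, 1 with the libraries numbered 2 and 3 only, 10 with those and the block, and 4 with overlapping genes summed and the block. It stayed 0 without any 1 library, with DESeq2 size factors and with either filter. In tumors (7) it was 1447 with DESeq2, 16 with limma-voom, 0 without the low-count filter, 0 with the replicate block (whose numbers do not pair the tumors), 0 to 1 without any 1 library, and 0 without control tumor 1 and midostaurin tumor 3. In 1 fit over all 12 libraries it was again 7, of which 2 were among the 7 above. For the difference (1) it was 99 with DESeq2, 3 with the stricter filter, 178 with the replicate block, H2-T3 not among them, 16 with the block in cells alone, 0 without the cell libraries numbered 1, and 1 to 6 without any 1 library, the highest without midostaurin tumor 4. The 7 tumor genes kept their direction in all alternatives, with adjusted p from 1.46e-25 to 0.416.

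Lists called in tumors (15) were 23 with the replicate block, 0 with an estimated correlation, and 1 with directional fry (7 with its mixed test). Lists called for the difference (10) were 15 with the replicate block, 11 with the block in cells alone, 0 with an estimated correlation, 0 with fry in either form and 4 to 11 without any 1 library, the lowest without midostaurin tumor 3, and 5 without control cells 2. Lists called in cells (0) were 0 to 8 without any 1 library, the highest without either library numbered 1, and 0 with the replicate block. The unpaired libraries left by that step shifted cell list medians to both sides, from -1.30 to 1.52 for type I interferon, -0.39 to 0.80 for chemokines, -0.21 to 0.25 for G1/S, -0.18 to 0.18 for mitosis, -0.47 to 0.48 for the unfolded protein response, -0.12 to 0.11 for cholesterol synthesis, -0.33 to 0.24 for SRF and YAP targets, and -0.21 to 0.19 for lysosome genes. The interferon difference between tumors and cells ranged from -1.32 to 1.64. Past the threshold, the median of immediate early and heat shock genes in cells was -0.21 without midostaurin cells 3 (adjusted p = 0.0164). For extracellular matrix in tumors, -0.03 with all libraries, it was 0.49 without control tumor 1 (adjusted p = 0.00936) and 0.45 without control tumor 1 and midostaurin tumor 3 (0.0443). Of 2449 values of named tumor genes under alternatives, 2314 kept their side of the threshold, 68 lost it and 67 gained it. For tumor lists these were 402, 47 and 43 of 492.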

Other observations

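The comparison of cell libraries by number and the choice of Irf1, Gbp5, Pthlh, Fat2, Runx2 and Kcnab2 in tumors were made after the values were seen. The interferon-gamma list was written before its values were seen, and its versions without shared members or without 1 library after.

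The cell libraries numbered 1 of both treatments differed from those numbered 2 and 3 in several gene lists. Ifi44, an interferon-induced gene, measured 80.9 and 80.5 CPM in the control and midostaurin libraries numbered 1 and 0.565 to 1.5 CPM in the other 4. All 28 tested genes of the type I interferon list were higher in the libraries numbered 1, with a median log2 difference of 2.17, where the median absolute difference between numbers 2 and 3 was 0.25. All 29 genes of the G1/S list were higher (median 0.60), and 24 of 26 lysosome genes were lower (-0.65). The unfolded protein and integrated stress response list had a median of 1.12, with Trib3 at 306 and 303 CPM against 21.6 to 26.0 CPM. All 5 chemokines were lower (median -2.11), while NF-kB targets went both ways, with 7 higher and 9 lower (-0.42). Lcn2, an iron-binding protein of inflammation, measured 2.3 and 2.79 CPM in the libraries numbered 1 and 158 to 172 CPM in the others, and Thbs2 measured 40.4 and 41.2 CPM against 325 to 396 CPM. Of 10447 genes, 761 differed more than 2-fold between number 1 and the mean of numbers 2 and 3, against 19 between numbers 2 and 3 and 8 between treatments. These are values of single libraries, with no test.

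Several tumor genes outside the edgeR threshold had no overlap between the groups. Pthlh, which encodes parathyroid hormone-related protein, measured 4.95 ± 1.94 CPM in controls and 34.7 ± 8.73 CPM with midostaurin (SD, n = 3 each), and Fat2, an atypical cadherin, 4.37 ± 0.899 and 19.3 ± 4.37 CPM. Runx2, a transcription factor of bone, measured 67.5 ± 5.00 and 121.7 ± 9.30 CPM, and Kcnab2 68.2 ± 10.1 and 23.8 ± 4.51 CPM. Each of these 4 had an adjusted p of 0.0654 with edgeR.

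The higher values of Cd274, Irf1 (log2 fold change 1.14, adjusted p = 0.0907 with edgeR), Gbp5 (1.29, 0.085) and Ciita led to the hypothesis that interferon-gamma response genes may be higher in treated tumors more widely. In a list of 30 such genes, 27 were above 0, with a median of 0.70, and 0.49 without midostaurin tumor 2, the lowest without any 1 library. Camera gave p = 1.05e-10 with the preset correlation and p = 0.0708 with an estimated correlation, the value set beforehand to decide, and directional fry gave p = 0.0372. Without midostaurin tumor 3 the p with an estimated correlation was 0.0449, and without any other 1 library 0.0614 to 0.142, while that of fry was 0.0282 and 0.0557 to 0.109. No member passed over all genes, while 9 were higher and 1 lower adjusted over the list alone, so the hypothesis stays open. The list was tested in the same tumors that gave the hypothesis, so its test is not independent of them. Psmb8, Psmb9, Nlrc5 and Ido1 had already been in lists tested here, and without these 4 the median was 0.75, the p with an estimated correlation 0.0967 and that of fry 0.0539.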
